A study of Homo sapiens with 11 samples.

How the data were processed

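Ribosome profiling and mRNA sequencing were carried out on HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, either wild type or knocked out for the enzyme that methylates the N6 position of the adenosine next to the cap of messenger RNA. The labels call the gene CSAM, and its current symbol is PCIF1. The 11 libraries made up 6 groups. The 5 footprint libraries comprised 1 wild-type library, 2 of knockout 1 and 2 of knockout 2, and the 6 RNA libraries comprised 2 of each genotype. The labels gave the wild-type RNA libraries the background numbers 1 and 2, while the wild-type footprint library carried none. Nothing in the labels stated whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

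Per the labels' protocols, ribosome-protected fragments were made with RNase I, ribosomes were pelleted, and the fragments were ligated to a preadenylated linker, depleted of rRNA, reverse transcribed and circularised before PCR. The RNA libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.1.0, TopHat2 2.0.9 and the genome build hg38, with no role or order. The program that made the counts, its strand setting and its treatment of reads shared by several transcripts were not given in the sources used here. The deposited files hold whole-number counts per transcript, not normalised, with 1 file per library and the same 182398 rows in the same order. Each row has a UCSC-style transcript identifier, a listed length and a count. The unit of the length is not stated. It was read as coding length in codons, since rows without a length (88482) held 0 counts in every library, and it served only to sort transcripts into classes. The lowest listed length was -9 and the highest 35982.

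Rows with identical counts were taken to be transcripts that repeat the same reads, which could not be checked without gene names. Of the 82937 rows with a count in some library, many had identical counts in all 11 libraries, and these were merged to 66016 features, each keeping the identifier and length of its first row. In 7553 merged rows the listed length differed from that of the row kept. Merging did not remove partly overlapping transcripts, so features were not independent, counts of called features exceed counts of genes, and p-values over sets of features are too small. The counts for the knockout mean over all lengths were therefore also given as the number of blocks of 20 consecutive lines that held such a feature, and the set tests were repeated with 1 feature per 20 lines, the one with the highest total count. Overlapping and antisense transcripts, paralogues and pseudogenes could not be told apart from these counts.

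Library totals over all rows were 10360220 to 21520682 for footprints and 49616803 to 77851238 for RNA, counting a read once for each row that held it. After merging, the totals were 8387752 to 17437453 and 40346318 to 63551193. Simulated data took the observed means and depths and, in every assay, the spread estimated jointly over all 11 libraries, with 200 changed features. The common dispersion was 0.0064 in RNA alone, 0.0039 in footprints alone and 0.0055 jointly. Features not tested for translational efficiency were all given the joint value, so their simulated spread in RNA may be too small. A 2-fold change in both knockouts was recovered for 78% of changed features in RNA (57346 tested). It was recovered for 47% in footprints (44145 tested) and 42% in translational efficiency (43816 tested). A log2 change of 0.5 was recovered for 32%, 8% and 3%, and unchanged features gave 20, 6 and 4 false calls.

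Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust estimation, two-sided, Benjamini-Hochberg adjustment over all features tested, threshold 0.05). Features needed at least 10 counts in at least 2 libraries of the assay, and TMM factors were computed within each assay. All libraries of an assay shared 1 estimate of the spread, so the lone wild-type footprint library was assumed to vary like the knockout pairs. In RNA, the chi-square per feature between replicates was 17.5 in wild type, against 6.29 in knockout 1 and 9.50 in knockout 2. That measure grows with depth, and the wild-type RNA libraries were the deepest. Whether wild type also varies more in footprints could not be tested. Translational efficiency was the change of footprints minus the change of RNA, tested as the interaction term of 1 model over all 11 libraries. The main comparison set the mean of both knockouts, equally weighted, against wild type. Each knockout was also compared with wild type and with the other. The SE printed for a feature's log2 change is the size of that change over the square root of the edgeR F statistic. Length classes were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 5 classes within each assay and comparison. With the preset correlation, camera takes its degrees of freedom from the number of features, not of libraries. With an estimated one, it takes the residual degrees of freedom of the fit, 3 in RNA, 2 in footprints and 5 in translational efficiency. Replicate pairs were compared before they were averaged: the chi-square per feature was 2.18 to 17.5, well above the value of sampling noise, so no pair was a library deposited in duplicate.

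The tests, filters, normalisation and most alternatives were chosen before the data were examined. The merging of identical rows, the length classes, the windows of 20 and 1000 lines and the comparisons along the table were chosen after the data were seen. Alternatives were DESeq2 size factors, no count filter, a mean count of at least 50, edgeR without robust estimation, DESeq2 1.42.0, limma-voom, the replicate number as a block, each replicate left out in turn and, for translational efficiency, TMM over all 11 libraries or limma with a separate spread per assay.

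The files do not pair identifiers with gene names. With the gene tables used here, 0 identifiers matched with their version and 6 without it, 1 of which held a count, and no match was used. The level of PCIF1, which would check the knockout labels, the gene lists drawn up beforehand and a comparison of transcripts by their first base were therefore not analysed here. The rule for named features, fixed before the data were examined, took those with the highest and lowest log2 fold changes among features with an edgeR adjusted p under 0.05, a mean CPM of at least 5 (in both assays for translational efficiency) and the same direction in both knockouts. It also asked for a gene symbol, which could not be applied. Without names, the single lowest and highest are given for RNA and for translational efficiency, a restriction made after the data were seen. Figures were drawn with matplotlib 3.10.9.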

Results

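The adenosine that follows the cap of many vertebrate messenger RNAs carries a methyl group at its N6 position, added by the methyltransferase PCIF1. The data collected here measured RNA abundance and ribosome occupancy in HEK293T cells with and without this enzyme, in 2 knockouts that the labels number, here called knockout 1 and knockout 2. RNA was sequenced in 2 libraries per genotype, and ribosome footprints in 2 libraries per knockout and 1 wild-type library. Library totals after identical rows were merged were 8760271 counts for wild-type footprints, 10519094 and 8387752 for knockout 1, and 17437453 and 9122052 for knockout 2. The RNA totals were 63551193 and 51327023 in wild type, 40346318 and 49580593 in knockout 1, and 46118849 and 44638751 in knockout 2. Across features, log2 CPM of replicate libraries correlated with r = 0.989 to 0.992 for footprints and 0.994 to 0.996 for RNA, against 0.971 to 0.982 and 0.979 to 0.986 between genotypes. In a principal component analysis of the RNA libraries, the first component (48.1% of the variance) separated knockout 2 from the other genotypes, and the second (31.0%) separated wild type from knockout 1.

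The first comparison asked which transcripts changed in abundance when the enzyme was lost. The deepest loss among eligible features was that of uc002jwh.4 (listed length 576). Its RNA level was 22.2 CPM ± 2.06 (SD, n = 2) in wild type, 2.02 ± 0.03 (n = 2) in knockout 1 and 1.69 ± 0.42 (n = 2) in knockout 2, a log2 fold change of -3.59 ± 0.12 (SE) with an edgeR adjusted p of 1.81e-19. Footprints of this transcript fell alongside, from 40.4 CPM in the wild-type library to 5.18 ± 0.35 (SD, n = 2) and 4.11 ± 0.71 (n = 2), with a log2 fold change of -3.15 ± 0.16 (SE) and an edgeR adjusted p of 4.14e-30. Its translational efficiency did not pass the test (log2 change 0.43 ± 0.21 (SE), edgeR adjusted p = 0.25). The highest rise was that of uc010skz.2 (listed length 857), from 6.12 CPM ± 0.53 (SD, n = 2) to 18.9 ± 0.01 (n = 2) in knockout 1 and 17.3 ± 1.13 (n = 2) in knockout 2. The log2 fold change was 1.57 ± 0.10 (SE) with an edgeR adjusted p of 1.11e-12. Footprints of uc010skz.2 rose from 1.32 CPM, which rests on 11 counts, to 6.64 ± 0.88 (SD, n = 2) and 6.98 ± 0.30 (n = 2). The translational efficiency of uc010skz.2 did not pass the test either (log2 change 0.79 ± 0.41 (SE)).

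Of 57719 features tested in RNA, 5078 differed between the mean of the knockouts and wild type (edgeR, adjusted p under 0.05). They comprised 2244 higher features in 938 blocks of 20 lines and 2834 lower features in 1110 blocks, of 8304 blocks tested. Most changes were small: 160 features rose and 473 fell by more than 2-fold, and the median size of a called change was 0.43 on the log2 scale. Knockout 1 alone gave 2458 calls (1256 higher, 1202 lower) and knockout 2 alone gave 7100 (3407 higher, 3693 lower). Transcripts with a long listed length, read as coding length, fell most often. In the class with a listed length over 800, 986 of 6732 features fell and 147 rose, with a median log2 change of -0.11 (camera adjusted p = 4.11e-08, and adjusted p = 0.068 with an estimated correlation). These class counts were 502 lower and 90 higher without wild-type replicate 1, and 432 and 70 or 567 and 65 without replicate 1 or 2 of knockout 1. The classes of 401 to 800 (median -0.03), 201 to 400 (0.02), 101 to 200 (0.02) and up to 100 (0.05) did not pass the camera test, with adjusted p from 0.10 to 0.15. With 1 feature per 20 lines, the classes of 201 to 400 (median 0.057), 101 to 200 (0.079) and up to 100 (0.12) did pass, with camera adjusted p of 0.0010, 1.57e-04 and 0.0010. The count for the knockout mean was 2532 without wild-type replicate 1, and 2032 and 2782 without replicate 1 or 2 of knockout 1, while the DESeq2 count was 2994. The count for knockout 1 was 601 and 754 without its replicates 1 and 2 and 1474 by DESeq2, and that for knockout 2 was 4156 without wild-type replicate 1, 4443 and 3364 without its own replicates 1 and 2, and 4338 by DESeq2.

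In RNA, 15 features in 6 blocks had at least 1 CPM in wild type and at most 3 counts over both libraries of knockout 1. The number in knockout 2 was 28 in 11 blocks, and 11 features in 3 blocks had at most 3 counts over all 4 knockout libraries. No feature (0) appeared in the knockouts at 1 CPM or more with at most 3 counts in wild type.

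The second comparison asked how ribosome occupancy changed. Footprints showed the opposite relation to listed length from that of RNA. In the class over 800, 490 of 5822 features rose and 71 fell, with a median log2 change of 0.13 (camera adjusted p = 2.02e-05). In the class of 401 to 800, 567 rose and 302 fell (median 0.08, camera adjusted p = 0.0093). In the class of 101 to 200, 1258 of 11812 fell and 352 rose (median -0.10, camera adjusted p = 0.0025), and in the class up to 100, 590 of 6111 fell and 186 rose (median -0.09, camera adjusted p = 0.035). With an estimated correlation the adjusted p was 0.10, 0.14, 0.10 and 0.29 in that order, so none of these classes passed. The class of 201 to 400 did not pass the camera test (adjusted p = 0.57), and its median (-0.01) and mean (0.03) differed in sign. With 1 feature per 20 lines it passed (median -0.059, camera adjusted p = 0.017), and the medians were -0.19 in the class up to 100, -0.17 in that of 101 to 200 and 0.053 in that of 401 to 800. Without replicate 1 of knockout 1 or replicate 2 of knockout 2, the class up to 100 had a camera adjusted p of 0.062 and 0.063, with medians of -0.09 in both cases. Its median was -0.14 without replicate 1 of knockout 2 and also with a mean count of at least 50. Without a count filter the medians of the classes up to 100 and of 101 to 200 were -0.018 (camera adjusted p = 0.089) and -0.063. In the class over 800, 110 features fell without replicate 1 of knockout 1.

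Over all lengths, 5007 of 44410 features differed in footprints between the knockout mean and wild type (edgeR, adjusted p under 0.05), with 2044 higher in 966 blocks and 2963 lower in 1251 blocks. Knockout 1 gave 2684 calls (1068 higher, 1616 lower) and knockout 2 gave 7021 (3171 higher, 3850 lower). Changes in RNA carried over to footprints in part. Of 1090 features called in RNA, taking 1 per 20 lines, 752 (69.0%) changed in the same direction in footprints, and the fold changes of the 2 assays correlated across 7731 features with r = 0.36. Features are not independent replicates. With 1 wild-type footprint library, no comparison with wild type could be set against the spread of wild-type footprints. DESeq2 called 1491 features in the knockout mean (403 higher, 1088 lower), 950 in knockout 1 (228 higher, 722 lower) and 1834 in knockout 2 (592 higher, 1242 lower), with a larger share lower (73.0%, against 59.2% by edgeR, in the knockout mean). The count for knockout 2 was 4273 without its replicate 1.

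The third comparison, of translational efficiency, asked whether occupancy changed beyond the change of RNA. Relative to all features, those with a long listed length gained efficiency and those with a short one lost it. Scaling within each assay hides any change of efficiency shared by all transcripts, and wild type has 1 footprint library. In the class over 800, 326 of 5819 features rose and 2 fell, and the median log2 change was 0.26 (camera adjusted p = 5.94e-17, and 0.0048 with an estimated correlation). The class of 401 to 800 had a median of 0.11, with 177 higher and 56 lower (camera adjusted p = 1.03e-04, and 0.0045 with an estimated correlation). In the class of 101 to 200, 893 of 11764 features fell and 53 rose (median -0.15, camera adjusted p = 7.49e-06, and 0.0041 with an estimated correlation). In the class up to 100, 442 of 5898 fell and 38 rose (median -0.18, camera adjusted p = 4.33e-05, and 0.032 with an estimated correlation). The class of 201 to 400 had a median of -0.04 and a mean of 0.01, which differ in sign, and a camera adjusted p of 0.18, or 0.032 with an estimated correlation. With 1 feature per 20 lines it passed (median -0.11, camera adjusted p = 5.64e-06), and the medians were -0.35 in the class up to 100, -0.27 in that of 101 to 200 and 0.062 in that of 401 to 800. Without a count filter the medians of the first 2 of these were -0.080 and -0.094. The counts of higher features in the classes over 800, 401 to 800, 101 to 200 and up to 100, in that order, were 182, 87, 33 and 21 without footprint replicate 2 of knockout 1, 213, 119, 35 and 21 without footprint replicate 1 of knockout 2, and 189, 91, 43 and 24 without RNA replicate 1 of knockout 1. By limma-voom they were 128, 45, 18 and 15. In the class of 401 to 800, limma-voom called 48 lower, so that neither direction prevailed, and the counts were 110 higher and 38 lower without footprint replicate 2 of knockout 2 and 32 lower without RNA replicate 1 of knockout 1. In the class over 800, 5 fell without footprint replicate 1 of knockout 1. Both knockouts showed the gradient, but both were compared with the same wild-type libraries, so their agreement is not independent. The median of the class over 800 was 0.20 in knockout 1 and 0.33 in knockout 2, and that of the class of 101 to 200 was -0.10 and -0.18.

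**Figure D1:**
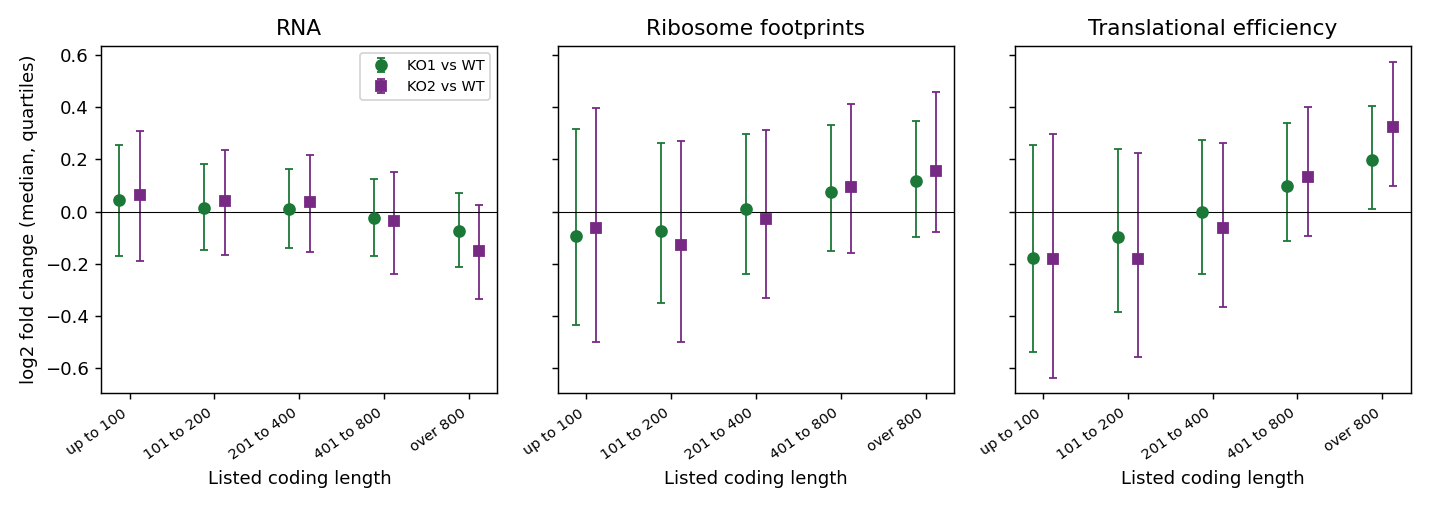
Median log2 fold change against wild type by class of listed length, read as coding length, for RNA (left), ribosome footprints (middle) and translational efficiency (right). Circles are knockout 1 and squares knockout 2, each the median over the features of a class, and bars span the lower to the upper quartile of features, not an error of the median. The median of the class over 800 lay below 0 in RNA and above 0 in footprints and translational efficiency in both knockouts. Both knockouts were compared with the same wild-type libraries.

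The gradient had a part in each assay. Over 7730 features, 1 per 20 lines and with a listed length of at least 20, the RNA change had a slope of -0.065 ± 0.0025 (SE over features) on the log2 scale per doubling of length and the footprint change a slope of 0.087 ± 0.0039, which add up to a slope of 0.152 ± 0.0035 for translational efficiency. The RNA part was 43.0% of that slope. Relative to the mean of the 3 genotypes, the RNA slopes of the libraries were 0.053 and 0.034 in wild type, -0.012 and 0.002 in knockout 1, and -0.048 and -0.030 in knockout 2. The difference of the knockout mean from wild type was 6.20 times its standard error, taken from the spread of libraries within genotypes (3 residual degrees of freedom). All wild-type slopes lay above all knockout slopes, and the slopes of the knockouts differed by 0.034. An exact permutation of the 15 splits of 6 libraries gave 0.067, the smallest p it can give, so that test could not pass the threshold. The footprint slopes were -0.058 in wild type, 0.001 and 0.017 in knockout 1, and 0.043 and 0.055 in knockout 2 (exact permutation p = 0.2, the smallest that 5 splits can give, so that test could not pass either). The largest slope between replicates was 0.019. As shares of counts over 1 feature per 20 lines, the class over 800 took 20.7% and 19.99% of wild-type RNA, 19.0% and 19.3% in knockout 1 and 17.6% and 17.7% in knockout 2. In footprints it took 16.6% (exact binomial 95% interval 16.6% to 16.7%) in the wild-type library, 18.4% and 18.5% in knockout 1 and 18.9% and 18.7% in knockout 2. The class of 401 to 800 took 32.6% of wild-type footprints, 32.1% in both libraries of knockout 1 and 32.8% and 33.3% in knockout 2, so its rise in the median footprint change had no counterpart in the shares of knockout 1. Such intervals cover counting error only.

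**Figure D2:**
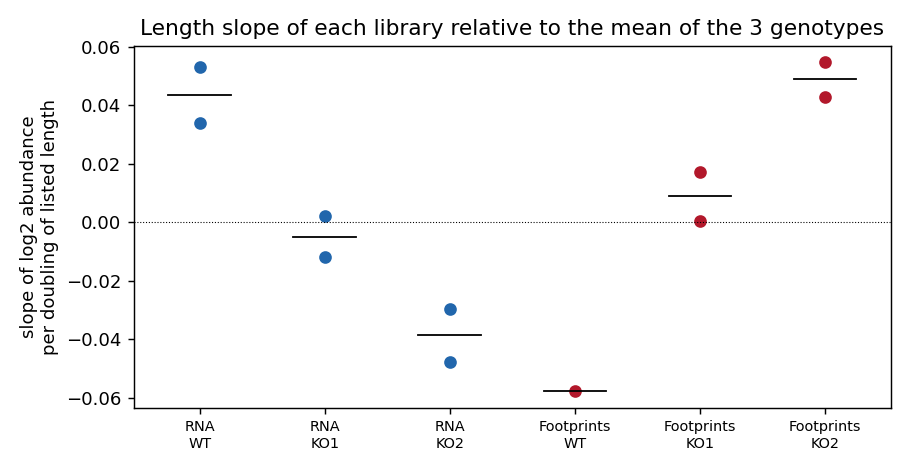
Slope of log2 abundance per doubling of listed length for each library, relative to the mean of the 3 genotypes of its assay. Each point is a library and each bar the mean of a group. Wild type has the highest slopes in RNA (0.053 and 0.034) and the lowest in footprints (-0.058, a single library).

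Over all lengths, 2477 of 44089 features changed in translational efficiency in the knockout mean (edgeR, adjusted p under 0.05), 685 higher in 349 blocks and 1792 lower in 792 blocks. Knockout 1 gave 537 calls (85 higher, 452 lower) and knockout 2 gave 3605 (1141 higher, 2464 lower). Among eligible features the lowest was uc063kpj.1 (listed length 22). Its footprints were 11.4 CPM in wild type, 4.02 ± 1.68 (SD, n = 2) in knockout 1 and 4.10 ± 0.04 (n = 2) in knockout 2, while its RNA was 5.87 ± 0.88 (n = 2), 6.62 ± 0.62 (n = 2) and 8.49 ± 0.62 (n = 2). The log2 change in efficiency was -1.83 ± 0.27 (SE) with an edgeR adjusted p of 4.04e-05. The highest was uc001yos.5 (listed length 1873), with footprints of 2.29 CPM in wild type, from 19 counts, 5.11 ± 0.54 (SD, n = 2) in knockout 1 and 8.17 ± 1.34 (n = 2) in knockout 2. Its RNA was 13.9 ± 1.72 (n = 2), 11.2 ± 0.46 (n = 2) and 13.9 ± 0.21 (n = 2), and the log2 change in efficiency was 1.65 ± 0.33 (SE) with an edgeR adjusted p of 0.0015. The count for knockout 1 was 865 without wild-type RNA replicate 2, 125 (6 higher, 119 lower) without its footprint replicate 2, and 121 and 126 without its RNA replicates 1 and 2. The count for knockout 2 was 2214 without its footprint replicate 1, and limma-voom called 1560 features in the knockout mean (235 higher, 1325 lower), 337 in knockout 1 (36 higher, 301 lower) and 2371 in knockout 2 (511 higher, 1860 lower).

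The knockouts were then set against each other. Among features called in both against wild type, 603 were lower and 503 higher in both in RNA, with 104 in opposite directions. Independent lists would share 76.9 and 74.1, but these lists share the wild-type libraries and are not independent. In footprints 1177 were lower and 687 higher in both, with 24 opposite (independent lists, 140.1 and 76.3), and in translational efficiency 413 were lower and 65 higher, with 0 opposite (25.3 and 2.2). The fold changes of the knockouts correlated with r = 0.46 in RNA, 0.72 in footprints and 0.77 in translational efficiency. Since both were compared with the same wild-type libraries, 5 simulations without any effect gave 0.45, 0.75 and 0.71. The knockouts shared at most 0 higher and 0 lower calls in RNA in these simulations. The values were 3 and 3 in footprints, and 1 and 1 in translational efficiency. The simulated spread was that estimated within groups, with 1 common value for features not tested for translational efficiency. A larger spread of those features or a larger deviation of the wild-type libraries is not covered. The covariance exceeded the simulated one by 0.093, 0.135 and 0.131. The controls could not be split into parts of at least 2 libraries, so part of the overlap may come from the shared controls.

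The direct test of knockout 1 against knockout 2 called 3772 features in RNA (2035 higher in knockout 1, 1737 lower), 3696 in footprints (2018 higher, 1678 lower) and 223 in translational efficiency (198 higher, 25 lower; edgeR, adjusted p under 0.05). The RNA count was 1584 (1025 higher, 559 lower) and 1352 (930 higher, 422 lower) without replicates 1 and 2 of knockout 1 and 2438 and 1928 without those of knockout 2. The footprint count was 1565 without replicate 1 of knockout 1 and 1618 and 2196 without those of knockout 2, and DESeq2 called 752. For translational efficiency the count ranged from 9 (all higher), without footprint replicate 1 of knockout 1, to 417, without wild-type RNA replicate 1. It was 76 and 51 (13 of the latter lower) without footprint replicates 1 and 2 of knockout 2, 45 and 48 without RNA replicates 1 and 2 of knockout 1, 148 without RNA replicate 2 of knockout 2, 412 without wild-type RNA replicate 2, and 88 by limma-voom.

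A run of consecutive lines of the count table held 399 of the 3693 features that were lower in RNA in knockout 2. Median changes were taken over windows of 1000 lines, a choice made after the data were seen, with 182 windows in each of 3 comparisons. In knockout 2, lines 85001 to 86000 had a median log2 RNA change of -0.64 (46 features, 84.8% lower) and lines 86001 to 87000 one of -0.79 (42 features, 100% lower). Both had a permutation p of 0.000999, the smallest that 1000 permutations give, where the largest window median after shuffling was 0.23 in size. Footprints changed by -0.91 and -0.66. In knockout 1 the same windows had medians of 0.13 (permutation p = 0.029) and -0.003 in RNA. Of 661 features tested in RNA in this run, 399 were called lower and 6 higher in knockout 2 against wild type (edgeR, adjusted p under 0.05). The permutations shuffled features over lines, so their p measures no spread between libraries. Neighbouring features may share reads, and both comparisons share the wild-type libraries. In all, 12 windows in knockout 1 and 15 in knockout 2 passed a permutation p of 0.05 corrected over the windows of their comparison. The largest of the others was lines 172001 to 173000, with a median of 0.32 in RNA and 0.37 in footprints in knockout 1 (45 features, permutation p = 0.000999, the smallest possible), and 0.07 and 0.12 in knockout 2.

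**Figure D3:**
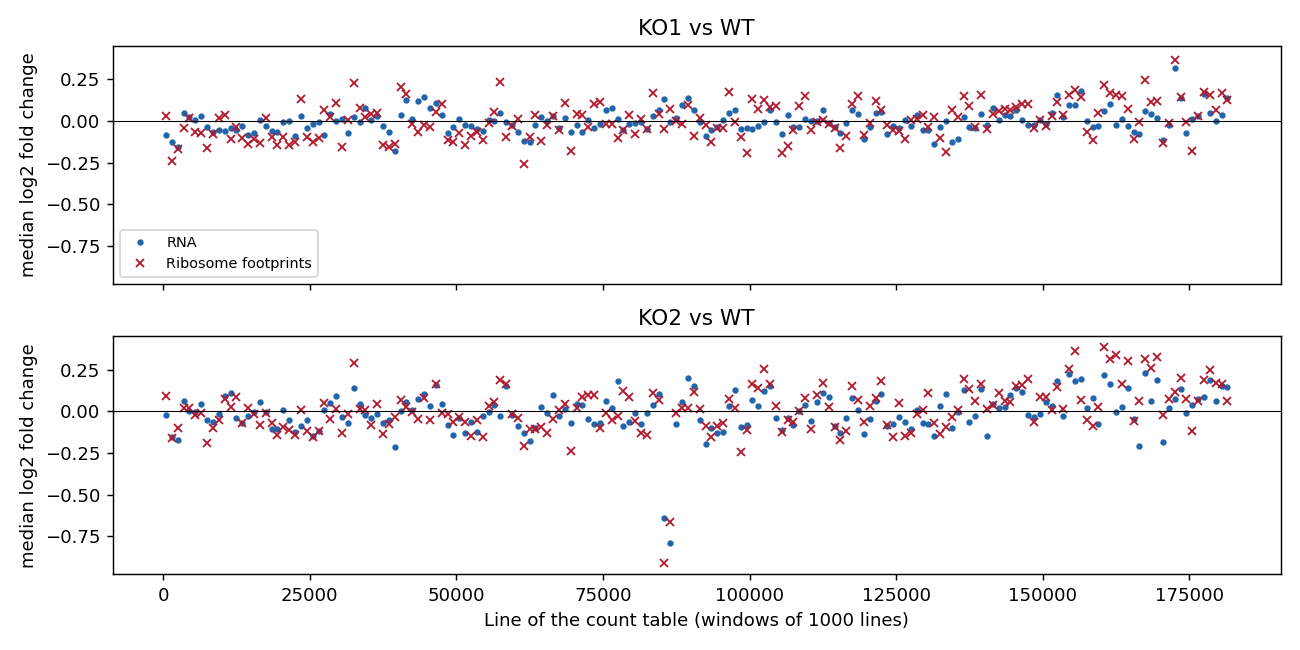
Median log2 fold change against wild type in windows of 1000 consecutive lines of the count table, for knockout 1 (top) and knockout 2 (bottom). Dots are RNA and crosses are ribosome footprints, each the median of a window with at least 20 features. In knockout 2 the windows at lines 85001 to 87000 stand apart, at -0.64 and -0.79 in RNA and -0.91 and -0.66 in footprints.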

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

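The test of the run with 1 feature per 100 lines was set out before its result was seen. The length classes, the tests of the length gradient and the test of RNA against footprints in the run were chosen after the result was seen.

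The knockouts differed from each other by the direct test of knockout 1 against knockout 2, with 3772 features in RNA, 3696 in footprints and 223 in translational efficiency (edgeR, adjusted p under 0.05). In RNA, the class over 800 was higher in knockout 1 by a median log2 change of 0.082 (camera adjusted p = 0.0026, and 0.18 with an estimated correlation). In translational efficiency, the median difference of knockout 1 from knockout 2 was 0.10 in the class of 101 to 200, 0.067 in that of 201 to 400, -0.029 in that of 401 to 800 and -0.13 in the class over 800, with camera adjusted p of 0.0019, 0.024, 0.024 and 3.78e-10, and 0.013, 0.013, 0.023 and 0.017 with an estimated correlation. Among the named features, uc001yos.5 had fewer footprints in knockout 1 than in knockout 2 (log2 change -0.64 ± 0.21 (SE), edgeR adjusted p = 0.040), and its translational efficiency did not pass that test (-0.32, edgeR adjusted p = 0.65).

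The gradient of translational efficiency with listed length was weighed first. Repeats of the same reads over many features do not account for it, since with 1 feature per 20 lines the median of the class over 800 was 0.22, against 0.26 over all features. The features kept may still hold reads shared with overlapping transcripts, which that comparison does not address. A length bias of the lone wild-type footprint library has no bearing on the RNA part of the gradient, since that library does not enter the RNA change. The RNA slope was -0.065 per doubling of length, against at most 0.019 between replicates, which is no test of that bias. For the footprint part (slope 0.087) such a bias cannot be told apart from the genotype, because wild type has 1 footprint library. The RNA part was larger than the scatter seen between replicate libraries of a genotype, since the difference was 6.20 times its standard error. That scatter has 3 residual degrees of freedom and may be technical, so scatter between separate cultures stays open. It would not show a length bias shared by the RNA libraries of a genotype. Such a bias cannot be told apart from the genotype by these values. Differences that separately kept lines may acquire without regard to the enzyme stay open, since the RNA slopes of the knockouts themselves differed by 0.034, more than replicates did and less than the knockout mean and wild type (0.065).

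The run of lines 85001 to 87000 that fell in knockout 2 was weighed second. Repeats of the same reads over neighbouring features do not account for it, since with 1 feature per 100 lines (20 features) the median RNA change was -0.66, against -0.75 with 1 per 20 lines (88 features). Reads that a kept feature shares with overlapping transcripts were not addressed. Fewer copies of that stretch of the genome in knockout 2 stay open and were not decided by the comparison of RNA with footprints. Both fell in both windows, but against wild type, with 1 footprint library, the medians did not match in each. The median footprint change differed from the median RNA change by -0.27 in lines 85001 to 86000 and by 0.13 in lines 86001 to 87000. Over the 88 features of the run, the medians were -0.75 in RNA and -0.79 in footprints. Set against knockout 1, they were -0.78 and -0.79. Equal falls would come with fewer copies and with lower transcription alike, so this comparison cannot tell these apart. A fall in transcription of the stretch with no loss of copies stays open as well, and that consecutive lines are neighbours in the genome was assumed. In knockout 1, which lacks the same enzyme per its label, the median RNA change of the run was 0.07.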

How the results depend on the processing

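The settings not chosen beforehand (identical rows not merged, 1 feature per 20 lines, the run of lines 85001 to 87000 left out, and an estimated correlation in camera) were chosen after the data were seen. No result past its threshold reversed, and the calls of all 4 named features held under every alternative that tested them (1 feature was not among those taken per 20 lines). Without a count filter, the medians of the class of 201 to 400, not past the threshold in either case, turned from -0.012 to 0.036 in footprints and from -0.036 to 0.011 in translational efficiency, where the median of all features was 0.044 and 0.060. Lower features were 52.0% of the RNA calls in knockout 2, but 49.1% with 1 feature per 20 lines and 49.7% without wild-type replicate 2. Between the knockouts they were 46.05% of the RNA calls, but 50.4% without the run. Other scalings, robust estimation, unmerged rows and leaving out the run kept every count of calls within 1.5 times. DESeq2 called 2994, 1474 and 4338 features in RNA for the knockout mean, knockout 1 and knockout 2 against wild type, and 1491, 950, 1834 and, between the knockouts, 752 in footprints. For translational efficiency limma-voom called 1560, 337, 2371 and 88 in the same order. Lower features were 73.0% of the DESeq2 footprint calls and 84.9% of the limma-voom calls in the knockout mean, against 59.2% and 72.3% by edgeR. With 1 feature per 20 lines, where fewer features were tested, the counts were 1404, 699, 1848 and 964 in RNA, 1193, 696, 1544 and 844 in footprints, and 670, 197, 929 and 68 in translational efficiency. The replicate number was not shown to pair the samples: deviations of same-numbered libraries correlated with r = -0.079 to 0.209 across features. As a block it gave 6599 calls in RNA, 5020 in footprints and 2834 in translational efficiency for the knockout mean, and moved a count by over 1.5 times only for translational efficiency between the knockouts (354 against 223).

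With each replicate left out in turn, the counts in RNA ranged from 2032 to 5591 for the knockout mean, 601 to 2836 for knockout 1, 3364 to 8127 for knockout 2 and 1352 to 5366 between the knockouts. In footprints they ranged from 4106 to 6454, 2034 to 3330, 4273 to 8297 and 1565 to 4295, and in translational efficiency from 1693 to 2883, 121 to 865, 2214 to 4282 and 9 to 417. A group left with 1 library was assumed to vary like the others, and the lone wild-type footprint library could not be left out. The median of the RNA class up to 100 ranged from 0.037 to 0.080 and passed without wild-type replicate 2, and that of the footprint class up to 100 ranged from -0.139 to -0.089 and missed the threshold in 2 of 4 cases. All 5 classes of translational efficiency kept their side of the threshold, with medians of 0.24 to 0.27 in the class over 800.

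An estimated correlation left the medians as they were and moved the adjusted p of camera over the threshold for the RNA class over 800 (median -0.11) and the footprint classes up to 100 (-0.089), 101 to 200 (-0.10), 401 to 800 (0.082) and over 800 (0.13). It brought the class of 201 to 400 in translational efficiency (-0.036) past the threshold. The estimated correlation was below the preset 0.01 in the footprint classes of 101 to 200 (0.0022), 401 to 800 (0.0073) and over 800 (0.0091). A larger correlation therefore did not raise the adjusted p of these 3 classes, and the degrees of freedom changed with the setting as well. The class of 201 to 400 in translational efficiency also passed with a mean count of at least 50 (-0.063) and with 1 feature per 20 lines (-0.11). In RNA, the class up to 100 passed with a mean count of at least 50 (0.066) and with 1 feature per 20 lines (0.12), as did the classes of 101 to 200 (0.079) and 201 to 400 (0.057) with the latter. In footprints, the class of 201 to 400 passed with 1 feature per 20 lines (-0.059), and the class up to 100 did not without a count filter (-0.018). Without that filter the medians of translational efficiency were -0.080 (up to 100) and -0.094 (101 to 200), against -0.18 and -0.15. The causes of the shifts with count filters or with 1 feature per 20 lines were not tested. Over these alternatives the camera adjusted p of the class over 800 in translational efficiency ranged from 6.45e-22 to 0.0048, against 1.66e-05 to 0.0049 for 401 to 800, 1.42e-17 to 0.0041 for 101 to 200 and 5.30e-14 to 0.032 for up to 100. In the class over 800 it ranged from 9.43e-10 to 0.068 in RNA and from 1.57e-06 to 0.10 in footprints. Classes were not tested with DESeq2, and the tests and settings meant for gene lists, first bases and the PCIF1 level were not run. Footprints, at lower counts than RNA and with 1 wild-type library, recovered fewer simulated changes.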

Other observations

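The change in translational efficiency also fell with RNA abundance, a relation examined only after the data were seen. Over 7731 features, 1 per 20 lines, sorted into quintiles by their mean RNA level, the median log2 change of the knockout mean against wild type was 0.15, 0.12, 0.04, 0.01 and -0.10 from the least to the most abundant. The medians fell at each step in the class over 800 (0.46, 0.35, 0.25, 0.21 and 0.13), in that of 401 to 800 (0.27, 0.16, 0.09, 0.04 and -0.08) and in that of 201 to 400 (0.07, -0.01, -0.08, -0.15 and -0.28). They did not in the class of 101 to 200 (-0.08, -0.17, -0.27, -0.35 and -0.34) or in the class up to 100 (-0.23, -0.32, -0.27, -0.34 and -0.49, from 36 to 59 features each). Within the most abundant quintile, the medians from the shortest to the longest class were -0.49, -0.34, -0.28, -0.08 and 0.13. The wild-type footprint library enters every one of these values, and so do the RNA levels used for sorting, those of the knockouts with a minus sign. A feature could also pass the count filter in footprints through knockout libraries alone. How much of the relation comes from these links was not tested.

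RNA and footprint changes went together more closely between the knockouts than against wild type. Across 7731 features, the correlation of the 2 assays' fold changes was r = 0.65 for knockout 1 against knockout 2, and 0.46 and 0.39 for knockouts 1 and 2 against wild type. Of 740 features called in RNA between the knockouts, 651 (88.0%) changed in the same direction in footprints, against 69.0% of 1475 for knockout 2 and 83.5% of 509 for knockout 1 against wild type. Without the run of lines 85001 to 87000, which fell in both assays in knockout 2, the correlations were 0.64, 0.45 and 0.37 over 7639 features, and the shares were 86.7%, 67.5% and 83.5%. The wild-type side rests on 1 footprint library. With log2 CPM and 1 footprint library on each side, r was 0.50 to 0.56 between the knockouts, 0.38 to 0.44 for knockout 1 and 0.31 to 0.36 for knockout 2 without the run. The difference between the shares was not tested, and the values without the run or with 1 library per side were taken after the data were seen.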
